A study of Mus musculus with 8 samples.

How the data were processed

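RNA from whole mouse kidneys was sequenced in 8 libraries. Per the labels, 4 libraries came from animals with a Six2-driven Cre recombinase, both alleles of Tfap2a floxed and 1 allele of Tfap2b floxed, and 4 came from control littermates given as WT. RNA was extracted with Trizol and a column kit, and libraries were made from total RNA with a directional kit, per the labels' protocols. The labels give no age, sex, litter, time of collection or sequencing batch.

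The deposited values are whole-number counts of reads per gene, 1 file per library, with no normalization. Per the submitters' processing notes, the tools used were STAR, an aligner, HTSeq, which counts reads per gene, and edgeR, and the genome build was mm9; their versions and the gene annotation are not given in the sources used here. Per the deposited file names, the counts were made without regard to strand, so reads of a gene and of an overlapping antisense gene were counted together or set aside as ambiguous. Reads that match several places equally well were set aside by the authors' counting. Genes with near-identical copies (Hspa1a and Hspa1b, Hba-a1 and its neighbour copy, C4a and C4b) therefore have uncertain levels. Each file ends with lines that name no gene, and these were kept out of library sizes and tests. Reads outside annotated genes made up 11.6% to 16.2% of all lines' counts, ambiguous reads 2.05% to 2.31%, and reads without a unique place 15.8% to 20.9%.

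Each file lists 37583 Ensembl gene identifiers, of which 32860 matched a symbol in GENCODE M21. The files hold no coordinates. Positions given here are those of GENCODE M21 on GRCm38, looked up by identifier, and no coordinate was converted from mm9. Counts assigned to genes totalled 13871861 to 16629301 per library, and 24618 genes had at least 1 count. A count of 0 in the library with the smallest effective size allows up to 0.223 CPM, from a floor of 3 counts. This floor covers counting error only, because PCR copies of a molecule are counted as separate reads.

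Libraries were grouped by their titles. Over all 28 pairs of libraries, counts differed by 10.8 to 85.5 times the sampling noise (chi-square per gene), so no library was a copy of another; the lowest values were for knockout 3 with wildtype 3 (10.8) and knockout 2 with wildtype 1 (14.3), and pairs within a group gave 18.1 to 58.7. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with robust dispersion, TMM normalization and the default filterByExpr filter (minimum count 10, minimum total count 15), which left 14433 genes. Genotype was the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors and 95% intervals of log2 fold changes were computed from the same fit. CPM values use TMM-scaled library sizes.

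A set of 32 gene lists with 341 distinct genes, covering nephron segments, other cell types, neighbouring tissues, injury, sex, time of day and handling, was fixed before the data were examined, as were the tests and most alternatives. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Mean log2 CPM of each list (prior count 2) was compared by an exact permutation test over 70 arrangements, which cannot give a two-sided p below 0.0286. Genes near the targeted genes were counted within 10 Mb and compared with all other placed genes by Fisher's exact test.

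The rule for named genes was also fixed in advance. It took the targeted genes and their family, the 12 largest changes in each direction among genes past the threshold, with a group mean of at least 1 CPM and no overlap between groups, and from each list up to 4 members with the lowest p and up to 2 of the most abundant. No gene qualified under the second part. A gene named outside this rule is given as chosen after its values were seen. Some genes that the rule takes are not reported here.

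On counts simulated for the comparison of both groups with 200 changed genes, over 14284 tested genes, the test recovered 74% of genes changed by 1 on the log2 scale and 95% of those changed by 2; it called 11 unchanged genes, and the 95% intervals held the true value for 95.3% of genes. In a second check, counts of 200 expressed genes were thinned in the libraries labelled knockout. Of these genes, 9.5% were called at a 1.5-fold reduction, 63% at 2-fold and 94% at 4-fold. When the p of each thinned gene was placed alone among the p-values of the unthinned genes, 0%, 15.5% and 72% were called.

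Alternatives were other normalizations, filters and windows, a fold minimum, DESeq2 1.42.0, limma-voom, a replicate block, and each library left out in turn. Fits without the libraries with adrenal, clock-gene or heat-shock patterns, with an adrenal term, and with adrenal and clock terms were added after seeing the data. Figures were drawn with matplotlib 3.10.9.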

Results

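The series compares whole kidneys of mice in which the transcription factor genes Tfap2a and Tfap2b were targeted in cells with a history of Six2, a gene of nephron progenitors, with kidneys of control littermates. The question was which kidney transcripts depend on these factors. There were 4 libraries labelled knockout and 4 labelled wildtype. Gene counts totalled 15763526, 15084836, 13871861 and 14530366 in knockout replicates 1 to 4, and 14721847, 16629301, 15791516 and 15636709 in wildtype replicates 1 to 4. Between 19486 and 20547 genes were detected per library. The labels do not say that each library came from a separate animal, and the p-values measure the spread between these libraries only. Group values are mean ± SD over 4 libraries, and log2 differences are knockout minus wildtype by label.

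Neither targeted gene was lower in the libraries labelled knockout. Tfap2a (ENSMUSG00000021359, chromosome 13, 40715302 to 40738376 on GRCm38), which encodes AP-2 alpha, was at 5.05 ± 0.99 CPM in the libraries labelled knockout and 4.22 ± 1.08 CPM in those labelled wildtype. The log2 difference was 0.26 (SE 0.24, 95% interval -0.26 to 0.78; edgeR adjusted p = 0.957). Tfap2b (ENSMUSG00000025927, chromosome 1, 19208914 to 19238576 on GRCm38), which encodes AP-2 beta, was at 80.0 ± 20.3 and 78.3 ± 20.5 CPM, a log2 difference of 0.03 (SE 0.22, 95% interval -0.46 to 0.53; edgeR adjusted p = 0.994). The directions below are therefore drawn from labels that the targeted genes' counts did not bear out. Gene-level counts include exons outside a deleted part, whole kidney holds cells without a Six2 history, and the deleted exons are not given in the sources used here.

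In single libraries, Tfap2a was at 5.65, 3.64, 5.12 and 5.81 CPM in knockout replicates 1 to 4 and at 4.08, 4.70, 5.31 and 2.78 CPM in wildtype replicates 1 to 4. Tfap2b was at 69.2, 103, 58.0 and 89.4 CPM in knockout replicates 1 to 4 and at 100.4, 51.8, 74.6 and 86.3 CPM in wildtype replicates 1 to 4. The family members Tfap2c and Tfap2d had at most 1 count in any library, and Tfap2e and Six2 had 0 counts in all 8, which allows up to 0.223 CPM in the shallowest. Kctd1 and Kctd15, whose proteins repress AP-2 factors, differed by 0.06 (SE 0.12) and 0.20 (SE 0.22) on the log2 scale. None of the 4 tested members of the TFAP2 and KCTD list passed the test over all genes or adjusted over the list alone, and camera gave adjusted p = 0.344.

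**Figure D1:**
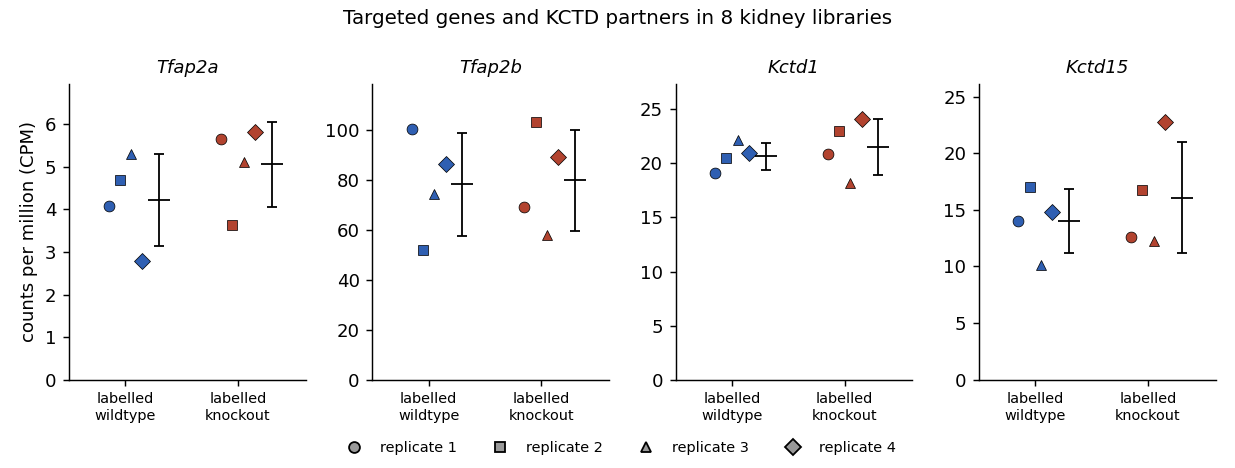
CPM (linear axis from 0) of Tfap2a, Tfap2b, Kctd1 and Kctd15 in each library, with 4 libraries per label, a marker shape per replicate number, and the mean ± SD beside each group. The values overlap in every panel, with group means of 5.05 and 4.22 CPM for Tfap2a and of 80.0 and 78.3 CPM for Tfap2b in the libraries labelled knockout and wildtype.

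Across the kidney transcriptome, no gene passed as higher or as lower in the libraries labelled knockout by edgeR's quasi-likelihood test among 14433 genes (smallest adjusted p = 0.957). At an unadjusted p under 0.05 there were 578 genes, 313 higher and 265 lower, against 722 expected by chance. This count depended on single libraries: it was 1252 without knockout replicate 3, 1250 without wildtype replicate 1 and 343 without wildtype replicate 2, and 403 to 536 without each of the others. The groups did not overlap for 284 genes, 1.97% of those tested, where chance gives 2.86%. The median absolute log2 difference was 0.12, and the 95% interval lay within 1 log2 unit on either side of 0 for 86.3% of genes.

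By limma-voom the count was also 0, with 592 genes at an unadjusted p under 0.05. DESeq2 called 1 gene higher and 3 lower, with 715 of 24562 tested genes at an unadjusted p under 0.05, since edgeR's filter on low counts was not applied there; these genes are named after their values were seen. Ndufs5, a subunit of respiratory complex I, was at 6.22 ± 4.82 CPM in the libraries labelled knockout and 0.39 ± 0.13 CPM in those labelled wildtype (log2 difference 4.00, DESeq2 adjusted p = 1.96e-05; edgeR adjusted p = 0.957). Lpl, the lipase that clears triglycerides from blood lipoproteins, was at 953 ± 142 and 1487 ± 196 CPM (log2 difference -0.64, DESeq2 adjusted p = 0.0473), and the collagen gene Col19a1 at 2.92 ± 0.31 and 6.39 ± 1.56 CPM (log2 difference -1.14, DESeq2 adjusted p = 0.0365). The fourth, ENSMUSG00000054588, was at 0.86 ± 0.48 and 3.98 ± 1.67 CPM (log2 difference -2.21, DESeq2 adjusted p = 0.0331). Leaving out 1 library gave 1 edgeR call without knockout replicate 3 (C4a, a complement gene), 1 without knockout replicate 4 (Ndufs5) and 2 without wildtype replicate 1 (the interferon-inducible GTPase genes BC023105 and Gm4841), and 0 otherwise.

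In none of the 32 gene lists did a member pass the test over all genes. As sets, 10 lists were higher and 2 lower by camera with its preset correlation, and 0 with an estimated correlation or by fry's directional test. Higher or lower as a set below means camera at the preset 0.01. Among the called lists the estimated correlation ran from 0.0924 (endothelium) to 0.944 (erythroid). The exact permutation test of list means gave p = 0.0286 for endothelium and 0.0857 (thin limb) to 0.371 (thick ascending limb) for the other called lists. Without knockout replicates 2 and 4, the libraries with the highest heat-shock transcripts, only the endothelial and podocyte lists were still called. That fit was chosen after seeing the data.

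Among nephron segments, transcripts of the thin limb, thick ascending limb and principal cells were higher as sets in the libraries labelled knockout, and those of the proximal tubule were lower. Cryab, a small heat-shock protein abundant in the medulla, was at 188 ± 36.1 CPM in the libraries labelled knockout and 119 ± 19.5 CPM in those labelled wildtype (log2 difference 0.66, SE 0.16). Aqp1, a water channel of the thin limb and proximal tubule, differed by 0.24 (SE 0.11). Of 9 tested thin limb genes, 6 were positive, and Cryab was the 1 that passed adjusted over the list alone. Camera gave adjusted p = 0.00792 for this list, and adjusted p = 0.491 with an estimated correlation; the call ended without knockout replicate 4.

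Umod, the abundant urinary protein of the thick ascending limb, was at 4524 ± 449 and 3970 ± 287 CPM in the libraries labelled knockout and wildtype, and the salt transporter gene Slc12a1 differed by 0.31 (SE 0.14). Casr, the calcium-sensing receptor, went the other way at -0.43 (SE 0.21). Of 15 tested thick ascending limb genes 12 were positive and 0 passed adjusted over the list alone (camera adjusted p = 0.0295; adjusted p = 0.529 with an estimated correlation). Aqp2, the vasopressin-regulated water channel of principal cells, was at 577 ± 231 and 334 ± 58.2 CPM, with 241 CPM in knockout replicate 3, and Aqp3 differed by 0.31 (SE 0.13). Of 13 tested principal cell genes 11 were positive and 0 passed adjusted over the list alone (camera adjusted p = 0.0295; adjusted p = 0.491 with an estimated correlation). The call for thick ascending limb ended without any of knockout replicates 1, 2 and 4 or wildtype replicate 2, and that for principal cells without knockout replicate 1 or 2 or wildtype replicate 2 or 4.

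In the proximal tubule, Slc7a13, an amino acid transporter of the straight segment, was at 1095 ± 241 CPM in the libraries labelled knockout and 1588 ± 175 CPM in those labelled wildtype (log2 difference -0.54, SE 0.16). Slc6a19, a neutral amino acid transporter, went the other way at 0.41 (SE 0.16), and Kap, the most abundant member, was at 38933 ± 10673 and 44088 ± 5942 CPM. Of 20 tested proximal tubule genes 15 were negative and 0 passed adjusted over the list alone (camera adjusted p = 0.0488; adjusted p = 0.572 with an estimated correlation). This call ended without knockout replicate 1 or 2 or wildtype replicate 2, 3 or 4.

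Apart from principal cells, no list of the distal segments, macula densa or progenitors was called as a set. The thiazide-sensitive cotransporter gene Slc12a3 of the distal convoluted tubule was at 451 ± 25.4 and 510 ± 105 CPM in the libraries labelled knockout and wildtype, Wnk1 differed by -0.21 (SE 0.10) and Egf by 0.07 (SE 0.12). Of 16 genes of this list 7 were positive and 9 negative, with a mean of 0.02, a median of -0.05 and a camera direction of lower (adjusted p = 0.514). In the connecting tubule, Calb1, a calcium-binding protein, differed by 0.18 (SE 0.20) and Trpv6, a calcium channel, by 0.83 (SE 0.38); the list gave adjusted p = 0.580 by camera. The intercalated cell genes Foxi1 and Atp6v0a4 differed by 0.39 (SE 0.27) and 0.13 (SE 0.09), and the list gave adjusted p = 0.140. Among 20 genes of magnesium and calcium handling 11 were positive, Slc41a3 differed by 0.42 (SE 0.22) and Fxyd2 by 0.06 (SE 0.12), and camera gave adjusted p = 0.730. For the macula densa, with Nos1 at 0.27 (SE 0.27) and Ptgs2 at 0.57 (SE 0.36), adjusted p was 0.736, and for nephron progenitor genes, with Sall1 at 0.16 (SE 0.22) and Pax2 at 0.06 (SE 0.13), it was 0.356. In these 6 lists 0 members passed adjusted over the list alone.

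Endothelial transcripts were higher as a set in the libraries labelled knockout. Differences were positive for all 12 genes tested, with a mean log2 difference of 0.22. Plvap, a protein of endothelial diaphragms, was at 125 ± 2.95 CPM in the libraries labelled knockout and 103 ± 5.02 CPM in those labelled wildtype. The vascular receptor genes Flt1 and Tie1 were at 62.8 ± 4.61 against 51.6 ± 1.71 CPM and at 34.8 ± 1.29 against 27.5 ± 3.18 CPM. These 3 genes did not overlap between the groups and passed adjusted over the list alone. Camera gave adjusted p = 8.62e-07 for the list, and adjusted p = 0.192 with an estimated correlation. Fry gave adjusted p = 0.0969 for movement in 1 direction and 0.0018 for change in either direction. The mean log2 CPM of the list was higher in every library labelled knockout (5.47 to 5.69) than in any labelled wildtype (5.29 to 5.43), which is the smallest p that the exact permutation test can give, 0.0286; adjusted over the lists it was 0.592. The camera call held without each library in turn (highest adjusted p = 0.00105).

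Podocyte and smooth muscle transcripts were higher as sets in the libraries labelled knockout. Wt1, a podocyte transcription factor, was at 2.81 ± 0.29 and 1.67 ± 0.90 CPM in the libraries labelled knockout and wildtype, and Podxl, which coats podocyte foot processes, at 92.3 ± 10.7 and 76.0 ± 15.3 CPM. Of 10 podocyte genes 9 were positive and 0 passed adjusted over the list alone (camera adjusted p = 0.00168; adjusted p = 0.491 with an estimated correlation), and the call ended without wildtype replicate 1. Ren1, renin, was at 82.4 ± 27.0 and 43.8 ± 25.0 CPM, and the contractile genes Acta2 and Tagln differed by 0.47 (SE 0.19) and 0.54 (SE 0.22). All 6 tested genes of juxtaglomerular and smooth muscle cells were positive and 0 passed adjusted over the list alone (camera adjusted p = 0.00168; adjusted p = 0.312 with an estimated correlation). The camera call for the juxtaglomerular and smooth muscle list held without each library in turn (highest adjusted p = 0.0342). It ended without the 2 heat-shock libraries (adjusted p = 0.409). For fibroblasts and pericytes, with Dcn at 0.21 (SE 0.14) and Rgs5 at 0.25 (SE 0.14), camera gave adjusted p = 0.266. Matrix genes, with Col6a1 at 0.47 (SE 0.23) and Fn1 at 0.15 (SE 0.21), gave adjusted p = 0.0501, and 0 members of either list passed adjusted over the list alone.

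Tubular injury transcripts were higher as a set in the libraries labelled knockout. Their list mean was highest in knockout replicate 1 (4.49 log2 CPM). That library also had the most reads outside genes (16.2%) and the highest erythroid mean (7.89 log2 CPM). Knockout replicate 3 had an injury mean of 3.74 log2 CPM and the fewest reads outside genes (11.6%). The lowest injury mean was in wildtype replicate 2, which was lowest in neither other measure. Read quality and other tissue as causes were not tested. Spp1, osteopontin, was at 841 ± 300 and 571 ± 116 CPM in the libraries labelled knockout and wildtype, and Clu, clusterin, differed by 0.22 (SE 0.16). Lcn2, an early injury marker, was at 4.60 ± 4.43 and 2.13 ± 1.08 CPM, with 11.1 CPM in knockout replicate 1. Of 16 injury genes 12 were positive and 0 passed adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.491 with an estimated correlation), and the call ended without knockout replicate 1 or wildtype replicate 2.

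Immune and proliferation lists were not called. Interferon response genes had mostly negative differences, with Gbp2 at 8.62 ± 1.72 CPM in the libraries labelled knockout and 14.6 ± 6.37 CPM in those labelled wildtype; 10 of 14 genes were negative and camera gave adjusted p = 0.0864. In the lymphocyte list, Ighm differed by -0.88 (SE 0.55), and camera gave adjusted p = 0.381. The macrophage genes Csf1r and Cd74 differed by -0.26 (SE 0.21) and -0.36 (SE 0.40), and their list gave adjusted p = 0.543. Il1b differed by 1.22 (SE 0.41) and Cxcl10 by -0.75 (SE 0.41) in the cytokine list (adjusted p = 0.732), and Rrm2 by 0.44 (SE 0.21) and Pcna by 0.19 (SE 0.17) in the cell cycle list (adjusted p = 0.382). In the interferon, macrophage, cytokine and cell cycle lists 0 members passed adjusted over the list alone.

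Of the lists of neighbouring tissues, adrenal and red cell transcripts marked single libraries. The adrenal genes Star, which brings cholesterol into mitochondria for steroid synthesis, and Hsd3b1, a steroid-synthesis enzyme, reached 350 and 225 CPM in knockout replicate 2 and 335 and 245 CPM in wildtype replicate 1, with at most 6.15 and 3.49 CPM elsewhere. The adrenal list gave camera adjusted p = 0.363. Urothelial genes were positive for 8 of 8, with Upk1b at 0.38 (SE 0.31) and Psca at 0.40 (SE 0.32); camera called them higher with adjusted p = 0.00558, against adjusted p = 0.491 with an estimated correlation, and not without wildtype replicate 2. Adipose genes, with Cfd at 0.64 (SE 0.62) and Fabp4 at 0.40 (SE 0.42), gave adjusted p = 0.0533. The red cell genes Hba-a1 and Alas2 were at 1241 and 145 CPM in knockout replicate 1, and 3 of 3 tested erythroid genes were positive (camera adjusted p = 0.0302; adjusted p = 0.491 with an estimated correlation); this call ended without knockout replicate 1 or 2 or wildtype replicate 2, 3 or 4. Of the skeletal muscle list only Mylpf was expressed enough to test (0.47, SE 0.39). In these 5 lists 0 members passed adjusted over the list alone.

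Handling, time of day and sex were read from their own lists. Heat-shock genes Hspa1a and Hspa1b, which respond to protein stress, were at 69.5 and 175 CPM in knockout replicate 2 and at 156 and 363 CPM in knockout replicate 4, with at most 11.9 and 41.4 CPM in the other libraries. All 10 immediate early and heat-shock genes were positive, and 0 passed adjusted over the list alone (camera adjusted p = 0.000429; adjusted p = 0.491 with an estimated correlation; call ended without knockout replicate 4). The circadian activator genes Arntl and Npas2, named after their values were seen, were at 24.3 and 18.3 CPM in knockout replicate 4 and 20.4 and 16.3 CPM in wildtype replicate 4, with at most 6.76 and 4.19 CPM elsewhere. Their targets Nr1d1 and Tef differed by -0.29 (SE 0.27) and -0.13 (SE 0.24), the list gave camera adjusted p = 0.730, and 0 members passed adjusted over the list alone.

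All 8 libraries had Y-linked transcripts, with Ddx3y at 72.1 to 92.3 CPM, and Xist, which silences the second X chromosome of females, at 0.57 to 1.00 CPM. Kdm5d differed by -0.29 (SE 0.13), and the sex chromosome list gave camera adjusted p = 0.301 with 0 members past the threshold adjusted over the list alone. The 6 genes known to be higher in male kidney were all negative, with Cndp2, a dipeptidase, at 1891 ± 598 and 2789 ± 628 CPM in the libraries labelled knockout and wildtype and Slco1a1 at 745 ± 493 and 1251 ± 443 CPM. Camera called this list lower (adjusted p = 0.00181, and adjusted p = 0.491 with an estimated correlation), and 0 members passed adjusted over the list alone. The call held without each library in turn (highest camera adjusted p = 0.0396) and ended without the 2 heat-shock libraries (adjusted p = 0.409). Of genes higher in female kidney, Cyp4a14 differed by 1.99 (SE 0.82), and Slco1a4, at -0.97 (SE 0.29), was the 1 that passed adjusted over the list alone; camera gave adjusted p = 0.326.

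**Figure D2:**
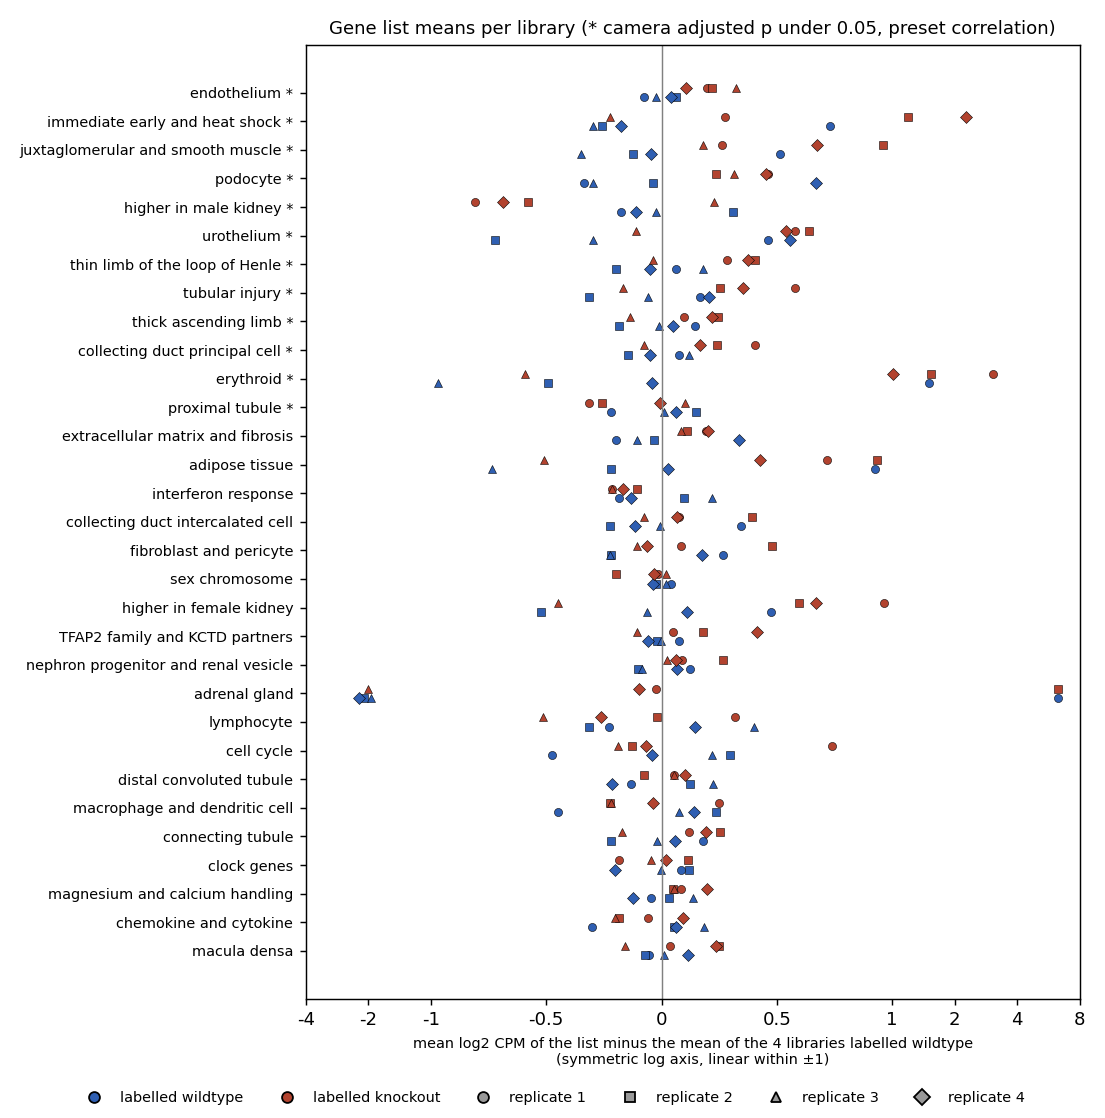
Mean log2 CPM of each gene list with at least 3 tested members, minus the mean of the 4 libraries labelled wildtype, per library; the horizontal axis is symmetric log and linear within 1 unit of 0, colours give the label and marker shapes the replicate number. Endothelial means lie higher in every library labelled knockout (5.47 to 5.69) than in any labelled wildtype (5.29 to 5.43), while the adrenal list sets knockout replicate 2 and wildtype replicate 1 apart.

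**Figure D3:**
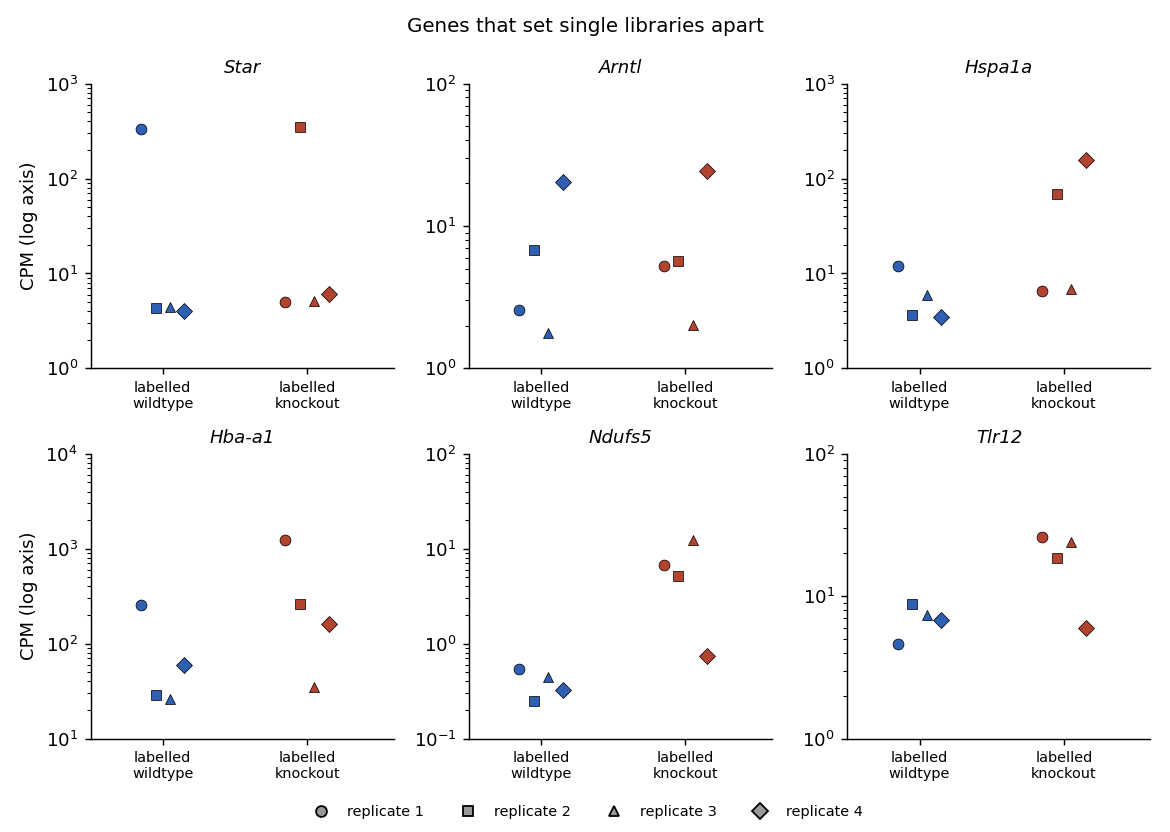
CPM (log axis) per library of Star, Arntl, Hspa1a, Hba-a1, Ndufs5 and Tlr12, with 4 libraries per label and a marker shape per replicate number. Star reaches 350 and 335 CPM in knockout replicate 2 and wildtype replicate 1 and at most 6.15 CPM elsewhere.

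Genes beside the targeted loci were examined because floxed alleles can carry flanking DNA of another mouse strain. With 0 edgeR calls in the whole comparison, 0 of 97 tested genes within 10 Mb of Tfap2a and 0 of 45 within 10 Mb of Tfap2b were called, and Fisher's exact test had nothing to place. At an unadjusted edgeR p under 0.05, a criterion added after seeing the data, 6 of the 97 genes near Tfap2a qualified (6.19%, against 3.97% elsewhere; odds ratio 1.59, 95% interval 0.567 to 3.63, Fisher's exact p = 0.287). Near Tfap2b 3 of the 45 genes qualified (6.67%, against 3.98% elsewhere; odds ratio 1.72, 95% interval 0.341 to 5.42, Fisher's exact p = 0.426). Within 20 Mb of Tfap2a there were 16 of 222 (7.21%, against 3.94%, Fisher's exact p = 0.0224), and within 5 Mb 1 of 41. A scan of windows over the genome, added after seeing the data, had a stronger excess on chromosome 13 at lower coordinates than Tfap2a. The window centred at 15 Mb held 10 of 79 such genes (12.7%, Fisher's exact p = 0.00114). Those centred at 20, 25 and 30 Mb held 10.7%, 10.6% and 9.78% (Fisher's exact p = 0.00982, 0.00666 and 0.011). Windows centred at 35 to 60 Mb held 4.95% to 6.87%. The windows overlap, and whether this stretch belongs to the flank of Tfap2a was not tested and stays open.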

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

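Of the tests in this part, those of Arntl, Npas2 and C4a for an outlying library were chosen only after the values were seen. Over library measures and list means, 76 groups of 4 libraries held 5 outlying libraries, where chance at 1 in 20 gives 3.8. Genes named by the rule gave 11 in 142 groups and genes chosen after their values were seen 3 in 20; no chance count is set beside these, because which genes to name was settled with their values known.

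Adrenal transcripts stood out in 1 library of each label. Star was at 350 CPM in knockout replicate 2 and 335 CPM in wildtype replicate 1, and Hsd3b1 at 225 and 245 CPM, each far outside the other libraries of its group, and the adrenal list mean was 7.53 and 7.48 log2 CPM in these libraries and at most 1.19 in the others. Between the labels that mean gave an exact permutation p of 0.514, and no other test of a biological explanation was run. Adrenal tissue in 2 libraries is a candidate explanation: of 6 further adrenal genes (Cyp11b1, Cyp11b2, Th, Dbh, Pnmt and Chga), which mark cortex and medulla and were too sparse elsewhere to be tested, 6 had their highest values in these libraries. Chga reached 49.1 and 68.6 CPM there and at most 0.0646 CPM elsewhere.

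Knockout replicate 4 stood apart in its group for the circadian genes Arntl (24.3 CPM) and Npas2 (18.3 CPM), and wildtype replicate 4 for Tef (294 CPM, the lowest of its group). Wildtype replicate 1 had the highest Hba-a1 (252 CPM), Alas2 (35.5 CPM) and Dnajb1 (58.1 CPM) of its group and the highest mean of immediate early and heat-shock genes (3.90 log2 CPM). Knockout replicate 3 stood apart in its group for Ren1 (122 CPM), Cndp2 (2786 CPM) and C4a (62.8 CPM), all the highest, and for Upk1b (5.57 CPM) and the urothelium list mean (1.70 log2 CPM), both the lowest. Knockout replicate 1 had the highest cell cycle list mean of its group (2.11 log2 CPM).

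Reads that no comparison used overlapped between the labels. Reads outside annotated genes made up 16.2%, 14.5%, 11.6% and 13.7% in knockout replicates 1 to 4 and 14.4%, 12.4%, 12.6% and 12.95% in wildtype replicates 1 to 4, so knockout replicates 1 and 2 lay above the highest library labelled wildtype and knockout replicate 3 was the lowest of all 8. Reads without a unique place made up 20.9% in knockout replicate 1, an outlying value in its group and above the highest library labelled wildtype at 18.4%; knockout replicates 2 to 4 were at 17.1%, 16.3% and 16.6%.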

How the results depend on the processing

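Fits without the libraries with adrenal, clock-gene or heat-shock patterns, with an adrenal term, with adrenal and clock terms, and the count near the targeted loci at an unadjusted p were chosen after seeing the data. The count of 0 genes in each direction by edgeR held under other normalizations, filters and robust off, by limma-voom, without the adrenal or clock-gene libraries and with either set of terms. A fold minimum can only remove calls, so its 0 says nothing. DESeq2 gave 1 higher and 3 lower; the cause was not tested. Leaving out 1 library gave 0 to 1 higher and 0 to 2 lower, and without the 2 heat-shock libraries 1 gene was higher. The 578 genes at an unadjusted p under 0.05 became 1252 without knockout replicate 3, 1250 without wildtype replicate 1 and 343 without wildtype replicate 2. Of the gene lists, 10 were higher and 2 lower by camera; with an estimated correlation 0 and 0, by fry 0 and 0, without the 2 heat-shock libraries 2 and 0, and with adrenal and clock terms 1 was lower. Leaving out 1 library gave 5 to 14 lists higher and 1 to 3 lower. Near Tfap2a 0 genes and near Tfap2b 0 genes were called within 5, 10 or 20 Mb, and at an unadjusted p 1 and 1 within 5 Mb, 6 and 3 within 10 Mb and 16 and 4 within 20 Mb. Over all single lists and alternatives, 68 calls were lost and 26 gained, and no called direction reversed; Tfap2a, Tfap2b and the list genes named by the rule kept their side of the threshold in all 2933 comparisons of a gene with an alternative.

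The labels do not say whether the replicate numbers pair the libraries, and the correlations are too few to settle it. Same-numbered libraries gave 0.23, -0.23, 0.28 and 0.29 for numbers 1 to 4. The highest correlation between labels, 0.45, joined knockout 2 and wildtype 1. The titles also carry serial codes, by which knockout 2 and wildtype 1, the libraries with adrenal transcripts, were neighbours. So were knockout 4 and wildtype 4, the clock-gene libraries, and knockout 3 and wildtype 3. This last pair had the lowest count difference of all pairs (10.8 by chi-square per gene). The other neighbours gave 14.3 to 41.7. What the codes stand for is not given, and an effect of their order was not tested. With the replicate block, edgeR called 0 genes higher and 0 lower, with 12 lists higher and 2 lower. At an unadjusted p under 0.05 there were 1075 genes with the block and 578 without it.

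Library sex was not used as a covariate because all 8 libraries had male transcripts, and limma-voom has no separate list calls because camera already ran on voom values. At 13871861 to 16629301 counts, 63% of 200 genes thinned 2-fold together were called, and 15.5% when each was judged as the only thinned gene; for 1.5-fold these were 9.5% and 0%. Tfap2a and Tfap2b thinned alone were not called over all genes at 2-fold (adjusted p = 0.957 for both) or 4-fold (adjusted p = 0.957 and 0.245). Taken as genes named in advance, they had unadjusted edgeR p of 0.019 and 0.0023 at 2-fold. At 4-fold these were 0.000129 and 1.7e-05. The log2 estimates were -0.69 and -0.96, then -2.18 and -1.96. Without thinning, the intervals began at -0.26 and -0.46, which leaves out a 2-fold fall in gene-level counts. For Tfap2b, with 1 allele floxed, a fall smaller than 2-fold is not left out. The 4-fold thinning goes beyond what loss of that allele alone could give.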

Other observations

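Of the tests in this part, the fit with adrenal and clock terms, the thinned genes judged one at a time, the limit of the first thinning result to 200 genes, the count of splits and the comparison with other windows of the genome were chosen only after the results were seen, and the genes below were chosen after their values were seen.

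The levels of 3 genes that passed edgeR's threshold only with 1 library left out were as follows. BC023105, an interferon-inducible GTPase gene, was at 10.1, 8.22 and 6.14 CPM in wildtype replicates 2, 3 and 4, at 0.48 CPM in wildtype replicate 1 and at 0.70 to 1.47 CPM in the libraries labelled knockout. Gm4841, another member of this family on chromosome 18, was at 4.51, 6.13 and 4.78 CPM in wildtype replicates 2, 3 and 4, at 0.14 CPM in wildtype replicate 1 and at 0.51 to 1.00 CPM in the libraries labelled knockout. C4a, a complement gene, was at 25.7, 27.4 and 22.1 CPM in knockout replicates 1, 2 and 4, at 62.8 CPM in knockout replicate 3 and at 57.9 to 80.8 CPM in the libraries labelled wildtype. The polycomb gene Phc2 differed little but did not overlap, at 61.1 to 65.8 CPM in the libraries labelled knockout and 52.8 to 54.0 CPM in those labelled wildtype (edgeR adjusted p = 0.957).

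No gene passed edgeR's threshold between the groups, with 578 at an unadjusted p under 0.05, 0 calls by limma-voom and 4 by DESeq2, and the targeted genes were not lower. Too little power for 2-fold changes in 200 genes at once is argued against by thinning, in which 63% were called. This does not reach changes in few genes, because many changed genes loosen the adjusted threshold: judged one at a time among the unthinned genes, 15.5% of the same 200 genes were called, so low power for a single changed gene stays open. Adrenal tissue and time of day that hide a genotype effect stay open too. The fit with adrenal and clock terms called 0 genes, with 747 at an unadjusted p under 0.05; in it 64% of 200 genes thinned 2-fold together and 15% judged one at a time were called. Without the 2 libraries highest in adrenal transcripts, edgeR called 0 genes, with 770 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0763. With 0 calls in the real split, all 35 of the 35 splits of the 8 libraries give as many by construction, so the count of splits says nothing on chance; the highest other gave 367. That split put knockout replicates 1, 2 and 4 with wildtype replicate 1, which points to a structure of the samples that the group labels do not give. The first principal component, with 34.4% of the variance, parted the same libraries. By the titles' serial codes, knockout replicates 1 and 2 and wildtype replicate 1 came first, and knockout replicate 4 came later. Several measures, chosen here after their values were seen, varied widely between libraries and are given for knockout replicates 1 to 4, then wildtype replicates 1 to 4, as list means in log2 CPM. The erythroid mean was 7.89, 6.36, 4.23 and 5.83, then 6.32, 4.33, 3.85 and 4.78, and the adipose mean 5.18, 5.40, 3.96 and 4.89, then 5.39, 4.24, 3.73 and 4.49. The mean of immediate early and heat-shock genes was 3.45, 4.36, 2.95 and 5.44, then 3.90, 2.91, 2.87 and 3.00. Genes higher in male kidney were at 9.72, 9.95, 10.76 and 9.84, then 10.35, 10.84, 10.51 and 10.42, and genes higher in female kidney at 4.11, 3.74, 2.70 and 3.82, then 3.62, 2.62, 3.09 and 3.26. Reads outside genes made up 16.2%, 14.5%, 11.6% and 13.7%, then 14.4%, 12.4%, 12.6% and 12.95%. In each of these measures, knockout replicates 1, 2 and 4 and wildtype replicate 1 lay to 1 side of the other libraries without overlap. The adrenal list mean parted the same libraries. Because the measures were chosen with their values known, this parting is a description and no test. Of the other lists called by label, the proximal tubule, thick ascending limb and smooth muscle means also parted the same libraries without overlap. Knockout replicates 1, 2 and 4 and wildtype replicate 1 were at 9.69 to 9.998 for proximal tubule, against 10.01 to 10.15 in the others. Thick ascending limb means were 6.66 to 6.81 against 6.38 to 6.61, and smooth muscle means 3.87 to 4.57 against 3.26 to 3.79. Means of the endothelial, podocyte, thin limb, principal cell, tubular injury and urothelial lists did not part them. The remaining lists are not given library by library. The genes, lists and targeted genes of that split were looked at, but groups picked from the outcome allow no test, so none of its fitted values are given. A wrong label, other tissue, handling, hormonal state, nephron segment content and read quality all stay open.

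Ndufs5 and Tlr12, both on chromosome 4, were high in knockout replicates 1 to 3 alone: Ndufs5 was at 6.66, 5.10 and 12.4 CPM there and at most 0.74 CPM elsewhere, and Tlr12, a pathogen-sensing receptor gene, at 26.1, 18.6 and 23.9 CPM against at most 8.83 CPM. A linked strain variant on chromosome 4 is a candidate explanation. Leaving out both genes, 20 of 252 genes within 10 Mb of Ndufs5 had an unadjusted edgeR p under 0.05 (7.94%, against 3.90% elsewhere; odds ratio 2.12, 95% interval 1.26 to 3.39, Fisher's exact p = 0.00300), and 5 of 409 overlapping windows elsewhere (1.22%) reached a p as low with an excess. Among these 5 windows was that centred at 15 Mb of chromosome 13, the chromosome of Tfap2a (10 of 79 genes, Fisher's exact p = 0.00114). The window around Ndufs5 was placed on a gene chosen for its difference, and neighbouring genes are not independent. Tie1 of the endothelial list is on chromosome 4 as well. Reads of Ndufs5 shared with near-identical copies, and a genotype effect in these libraries, were not tested and stay open.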
